A study of Escherichia coli with 6 samples.

How the data were processed

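Total RNA of Escherichia coli K-12 MG1655 was measured on 6 custom Agilent arrays, 1 per culture. Per the labels, the cells carried a plasmid with wild-type (WT), G181D or R258C NusA, the chromosomal copy had been removed by P1 transduction, and each group had 2 biological replicates. The labels give growth at 37 °C after a 1% subculture to an optical density of 0.4, and 500 ng of RNA per labelling with Cy3. The 2 arrays of each group shared 1 slide, so slide, scan and group cannot be told apart. No other batch is named in the labels.

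The deposited scanner files were made by the authors with Agilent Feature Extraction 11.5.1.1 and give, per spot, intensity values: the processed signal (intensity after background subtraction and spatial detrending, not scaled between arrays), the mean spot intensity and the median local background intensity. They also give 0 or 1 marks for spots well above background, for saturation and for outlier spots. The deposited value table holds log2 values that, compared with the scanner files, equal the log2 processed signal minus the 75th percentile of each array, and its columns for G181D replicates 1 and 2 hold each other's scanner values. The scanner files were used, with the value table as an alternative.

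Each array has 420288 spots, of which 416505 are not controls, for 415272 probes of 60 bases. Overlapping probes read as a single sequence with 0 disagreements, so all probes read the plus strand of the chromosome. Gene coordinates and names came from the RefSeq table of assembly ASM584v2, to which 4150 of 4374 gene names in the files matched. The strand of a gene was read from its sequence as pieced together from the probes, which gave 4253 of 4290 coding genes, 2067 on the plus strand and 2186 on the minus strand. For plus-strand genes the signal was taken as sense, and for minus-strand genes as signal of the opposite strand. The plan was to assign probes by the gene column of the files. Before any group comparison, 55.9% of the gene-labelled probes were found to cross the left edge of the gene they name, and 90.2% of probes labelled intergenic to lie wholly inside a gene. Probes were therefore assigned by position: 227429 probes lying wholly inside exactly 1 gene, at 1 position and not listed as cross-hybridising were used. The gene column was run as an alternative. A plus-strand gene with a probe had a median of 32 probes. Probes were unevenly spaced: 196 of 4096 genes had over 20 used probes per 100 nt, against a median of 3.78, so the mean of such a gene weighs its densely covered parts more.

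The level of a gene was the mean over its probes of the log2 processed signal minus the 75th percentile of that array. A gene was tested when it had at least 3 probes and at least 50% of them were well above background on both arrays of at least 1 group. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior, 3 groups of 2 arrays, no covariates, package data.table in version 1.17.8, statmod 1.5.0), with Benjamini-Hochberg adjustment and a threshold of 0.05. A further count asked for a log2 change of at least 1. All tests were two-sided. The same test was run on opposite-strand signal and on the difference between the last and the first of 3 equal parts of a gene, for plus-strand genes with at least 3 probes in each part. The residual degrees of freedom were 3. The number of arrays limits the precision: the median standard error of a log2 change was 0.53 for plus-strand genes. Of the non-control spots, 91.0% to 95.3% per array were well above background and 0 were saturated.

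Before the data were examined, 25 gene lists, the main tests, the alternatives and the rule for named genes were fixed. Lists with at least 3 tested plus-strand members, 22 of the 25, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists and both mutants. For R258C against G181D the plan named a test of genes only. The lists were also tested there, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The lists reported cover the nusA operon, transcription elongation and termination factors, ribosomal proteins, the cryptic prophages Rac, e14, DLP12, Qin, 3 P4-like prophages, and CPS-53, CPZ-55 and KpLE2 together, leader-attenuated amino acid operons, the SOS response, heat shock, envelope stress, RpoS-dependent stress, flagella and chemotaxis, sugar catabolism, anaerobic respiration, the TCA cycle with aerobic respiration, surface polysaccharide operons, fimbriae and curli, iron uptake, nucleotide synthesis, arginine and methionine synthesis, and plasmid or transduction markers. Named genes were, per mutant against WT and direction, up to 8 with the largest change among genes past the threshold, apart from both WT arrays and well above background, without insertion sequences and repeated genes. Where fewer than 5 passed, the 5 with the largest moderated statistic were taken as not passing, with 5 each way for the mutants against each other. From each tested list up to 4 members with the smallest p were added, and a few fixed genes always, among them nusA, its neighbours, nusG and tnaA. Genes named outside the rule are marked as chosen after their values were seen.

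On simulated arrays with the spread of these data and 200 changed genes among 1927 in G181D against WT (20 draws), the gene test recovered 0.373% of changes of log2 1, 11.3% of log2 2 and 71.7% of log2 4, and 4.80% of its calls were false. For opposite-strand signal (1998 genes) the shares recovered were 2.16%, 39.6% and 88.9%, and for the difference along the gene (1607 genes) 52.1%, 89.1% and 98.1%. A list of 20 genes shifted by log2 1 was called in 100% of draws at the preset correlation and in 0% with an estimated correlation, and 0.526% of unshifted lists were called at the preset correlation. Genes were simulated independently, with the same spread in every group, and lists were filled with random genes. The 0.526% therefore does not cover the real lists, whose members can move together from array to array. The correlation of the mutants' responses was set beside 100 simulated draws of unchanged mutants against a shared WT pair.

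Alternatives were normexp background correction with an offset of 50, median scaling, quantile normalization, no filter, a stricter filter, the median over probes, the deposited value table, the replicate number as a block, only the groups compared, a trended robust prior, and each array left out in turn. After the data were seen, the gene column of the files, array weights and the omission of WT replicate 2 together with G181D replicate 2 were added. Scaling alternatives moved the median of all tested genes by over 0.1 in places: with median scaling to -0.21 in G181D, to -0.10 in R258C and from -0.10 to 0.02 in R258C against G181D, and with normexp to -0.10 in R258C.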

Results

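Plus-strand signal was measured along the whole chromosome in cells whose only intended source of NusA, the transcription elongation and termination factor, was a plasmid with the WT, G181D or R258C form. Each group had 2 arrays. The 75th percentile of the processed signal was 730 and 290 on the WT arrays, 611 and 344 on the G181D arrays, and 738 and 534 on the R258C arrays. Levels below are log2 signal relative to that percentile, and each ± is an SD with n = 2.

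The gene under study was checked first. nusA (b3169, minus strand, 3316039 to 3317526 in assembly ASM584v2) was read by 60 probes as opposite-strand signal. Its level was 4.41 in WT replicate 1, 3.14 and 4.91 in G181D, 4.92 and 4.24 in R258C, and -1.47 in the library labelled WT replicate 2. Relative to the mean of its minus-strand neighbours rimP, a ribosome maturation factor, and infB, translation initiation factor 2, nusA stood 4.33 higher in WT replicate 1, 2.44 and 4.05 higher in G181D, and 4.39 and 3.42 higher in R258C. In the library labelled WT replicate 2 this difference was -0.51. A scan for runs of at least 3 genes without signal found 2 chromosomal stretches, in that library alone. They run from recT to stfR in the Rac prophage (1413984 to 1432411) and from aldA to narV (1488232 to 1536617). Outside both, its signal was also low in the 1-kb bins at 1397000, 1398000 and 1399000. Its means there were -5.99, -5.97 and -5.45, against 0.92, -1.52 and -1.31 in WT replicate 1. Labels were kept as given, and every WT mean below includes that library.

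**Figure D1:**
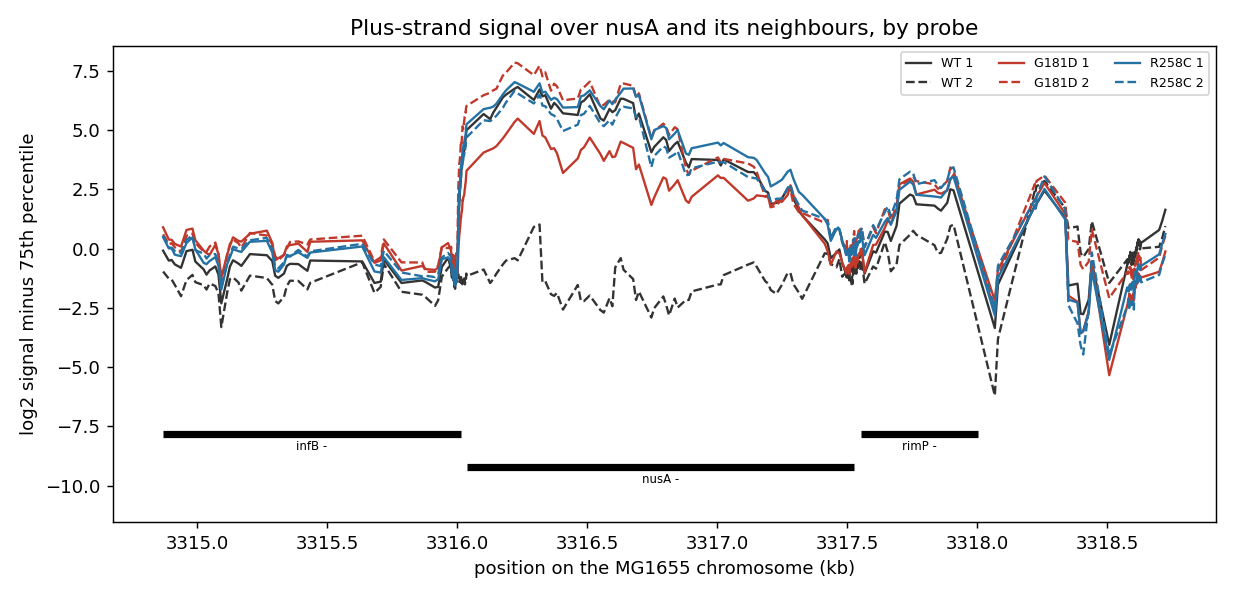
Log2 signal minus the 75th percentile of each array, by probe, against position in kb over nusA, infB and rimP, with 1 line per array. On 5 arrays the signal over nusA averages between 3.14 and 4.92, and on the array labelled WT 2 it averages -1.47.

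**Figure D2:**
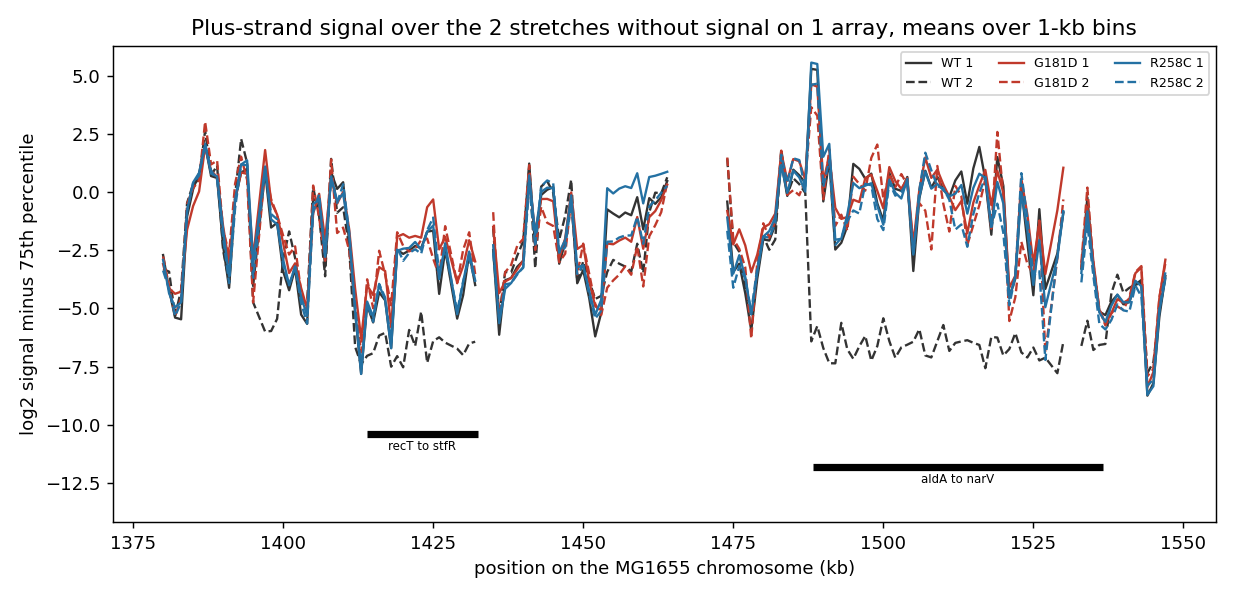
Mean log2 signal minus the 75th percentile of each array in 1-kb bins against position in kb, with 1 line per array. Over the bars recT to stfR and aldA to narV, the median gene level is -6.86 and -6.61 on the array labelled WT 2, and -2.52 and -0.10 over the other 5 arrays. Outside the bars, the bins at 1397000, 1398000 and 1399000 lie at -5.99, -5.97 and -5.45 on the array labelled WT 2.

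Across probes, the library labelled WT replicate 2 and G181D replicate 2 each had Pearson correlations of 0.828 to 0.894 with every other array, and the remaining 4 arrays correlated at 0.956 to 0.982 with each other. These correlations are across probes, which are not independent replicates. The SD over genes of the difference between replicates was 1.55 in WT, 1.42 in G181D and 0.52 in R258C.

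The comparison of G181D with WT asked which transcripts differ when NusA carries the G181D change. Genes for the flagellum and chemotaxis were lower in G181D: the median change of the 29 measured members was -3.92, with 28 below 0, and camera gave an adjusted p of 8.8e-43 (adjusted p = 0.583 with an estimated correlation). fliJ, a chaperone of flagellar export (b1942, 2017946 to 2018389), fell from 0.43 ± 0.24 in WT to -3.82 ± 0.08 in G181D, 19.0-fold (log2 change -4.25, SE 0.36). fliO (b1947, 2021504 to 2021869), fliP (b1948, 2021869 to 2022606) and fliQ (b1949, 2022616 to 2022885), which encode parts of the export gate, fell by 3.92, 3.70 and 3.46 (SE 0.37, 0.37 and 0.36), and fliI, the export ATPase (b1941, 2016554 to 2017927), fell by 3.48 (SE 0.35). In each of these 5 genes both G181D arrays lay below both WT arrays. The member above 0 was trg, a chemoreceptor gene (b1421) chosen after its values were seen, which lies in the aldA to narV stretch. Its change of 3.13 did not pass (adjusted p 0.934), with a level of -6.13 in the library labelled WT replicate 2 and -2.24 in WT replicate 1.

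Of 1927 plus-strand genes tested with limma, these 5 passed in G181D, all lower, each with an adjusted p of 0.0497, and each changed by a log2 of over 1. At an unadjusted p under 0.05 there were 99 genes, where chance gives about 96.4. Among the flagellar list, 22 genes were lower when adjusted over the list alone. The count of 5 rests on single arrays: it became 47 without WT replicate 1 (32 higher and 15 lower), 13 without G181D replicate 1 (12 higher and 1 lower, fliJ), and 0 without any of WT replicate 2, G181D replicate 2, R258C replicate 1 or R258C replicate 2. Of the 47, 30 lie in the stretches without signal in the library labelled WT replicate 2 and 13 are flagellar, among them the 5. It was also 0 with normexp, no filter, the median over probes, the replicate number as block, only the groups compared, the trended robust prior, the gene column of the files and array weights. The adjusted p of these 5 genes ranged from 0.00507 to 0.441 over the alternatives, while their changes stayed between -4.47 and -2.18. Without both WT replicate 2 and G181D replicate 2, 44 genes passed, 28 lower and 16 higher, 23 of them flagellar. That fit leaves 1 residual degree of freedom, from the R258C pair, and assumes that the lone arrays vary alike. The list's median was -3.46 without WT replicate 2.

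**Figure D3:**
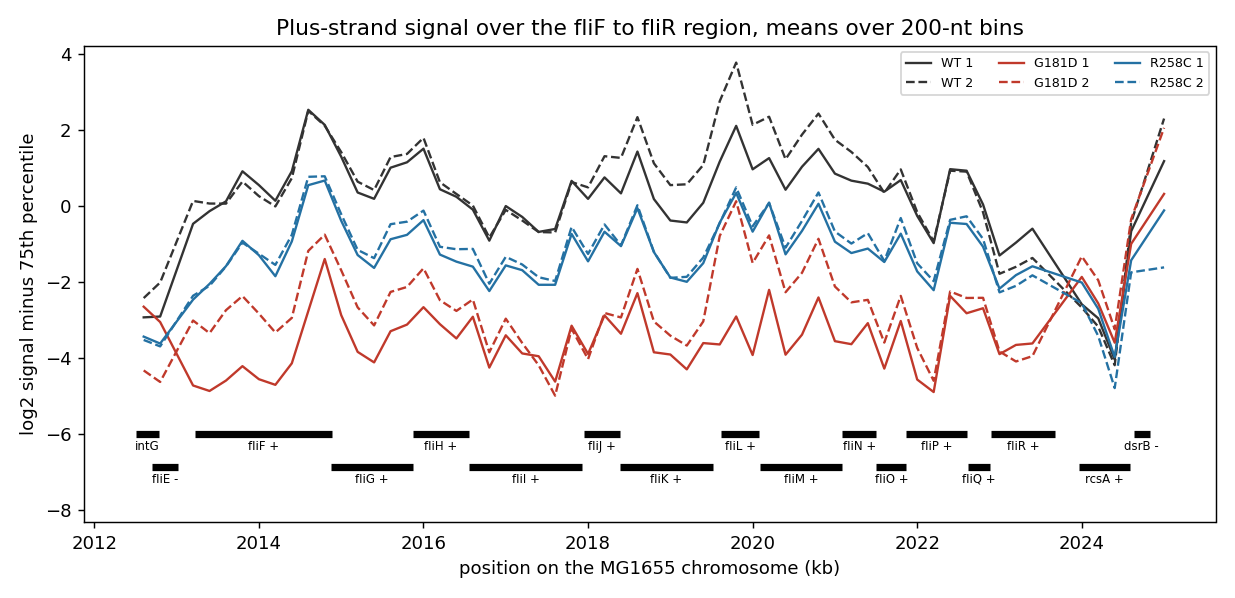
Mean log2 signal minus the 75th percentile of each array in 200-nt bins against position in kb over fliF to fliR, with 1 line per array and genes as bars. For fliJ the G181D arrays lie at -3.76 and -3.88, the R258C arrays at -1.35 and -1.16, and the WT arrays at 0.26 and 0.60.

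Other lists shifted as sets in G181D, but none of their members passed alone. Genes of the cryptic prophage DLP12 were higher by a median of 2.14-fold, all 17 members above 0 (camera adjusted p 3.0e-08, and adjusted p = 0.618 with an estimated correlation). Both G181D arrays exceeded both WT arrays in 12 of the 17. Examples are ybcW (2.32, SE 0.66), tfaX (1.27, SE 0.34), tfaD (1.20, SE 0.38) and appY, a transcription activator (1.86, SE 0.61). The median log2 change was 0.59 under normexp background correction. The 10 measured heat shock genes were lower by a median of -0.60, all below 0 (adjusted p 1.7e-04, and adjusted p = 0.583 with an estimated correlation). They include the chaperonin genes groL (-1.69, SE 0.49) and groS (-1.43, SE 0.39), and the chaperone genes htpG (-1.32, SE 0.36) and dnaK (-1.21, SE 0.46). Without WT replicate 1 the heat shock median was -0.40 and did not pass, and without WT replicate 2 it was -0.97. It was -0.31 with the gene column of the files.

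RpoS-dependent stress genes were lower by a median of -0.81, 14 of 15 below 0 (adjusted p 3.2e-04, and adjusted p = 0.706 with an estimated correlation). Among them, glaH, a glutarate hydroxylase gene, had a change of -2.60 (SE 0.78), osmC, a peroxiredoxin gene, -0.82 (SE 0.42), and aidB -0.81 (SE 0.48). gadE, an activator of acid resistance, went the other way (1.00, SE 0.92). Without WT replicate 1 the RpoS median was -0.22 and did not pass, and without WT replicate 2 it was -1.23. Sugar catabolism genes were lower by a median of -0.33, 15 of 23 below 0 (adjusted p 0.00416, and adjusted p = 0.706 with an estimated correlation), including the sorbitol uptake genes srlA (-3.38, SE 0.91) and srlE (-3.21, SE 0.85) and the maltose genes lamB (-2.56, SE 0.74) and malM (-2.88, SE 0.92). That median was -0.50 without WT replicate 1 and -0.17 without G181D replicate 1, where it did not pass, and -0.62 without WT replicate 2, -0.79 without G181D replicate 2, -0.55 with median scaling and -0.56 without WT replicate 2 and G181D replicate 2 together.

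In the TCA cycle and aerobic respiration list, all 10 members were below 0 in G181D, with a median of -1.24 (adjusted p 1.6e-05, and adjusted p = 0.706 with an estimated correlation). Examples are sucD (-1.48, SE 0.73), sdhD (-1.33, SE 0.61), sdhC (-1.17, SE 0.55) and acnB (-0.96, SE 0.44). Anaerobic respiration and fermentation genes were higher by a median of 2.14-fold, 21 of 22 above 0 (adjusted p 1.0e-04, and adjusted p = 0.706 with an estimated correlation). dmsA, a subunit of dimethyl sulfoxide reductase, stood at 4.37 in G181D replicate 2 and between -2.45 and -1.41 on the other 5 arrays. The genes nirB, nirC and nirD had changes of 1.65, 1.63 and 1.66 (SE 0.71, 0.54 and 0.81). Without G181D replicate 2 neither list passed, with medians of -0.32 and -0.15, and without G181D replicate 1 the medians were -2.12 and 1.92. The anaerobic median was 0.96 without WT replicate 1, where it did not pass, and 0.68 with normexp. Without WT replicate 2 and G181D replicate 2 together, neither list passed (-0.27 and 0.14).

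Fimbriae and curli genes were higher in G181D by a median of 0.81, all 18 above 0 (adjusted p 4.3e-05, and adjusted p = 0.706 with an estimated correlation), with fimE, a recombinase that switches fimbriae off, at 1.88 (SE 0.62) and fimA, the main fimbrial subunit, at 1.42 (SE 0.86). The median was 0.28 without WT replicate 2 and 0.38 without G181D replicate 1, where it did not pass, 1.46 without G181D replicate 2 and 0.46 with normexp. Rac prophage genes were higher by a median of 2.53, all 11 above 0 (adjusted p 3.7e-06, and adjusted p = 0.706 with an estimated correlation), including sieB (2.65, SE 0.80) and stfR (2.54, SE 0.90). Most of this change came with the Rac stretch without signal in the library labelled WT replicate 2: the median was 0.34 without that library and did not pass. Of 18 alternatives, only that 1 lost the call. The Rac median was 1.01 without WT replicate 2 and G181D replicate 2 together, 0.79 with normexp and 4.47 without WT replicate 1. In the Rac stretch only 19.5% of probes were well above background in the library labelled WT replicate 2, so changes against that library are not exact. Prophage e14 genes had a median of 0.52, 8 of 10 above 0 (adjusted p 0.0373, and adjusted p = 0.706 with an estimated correlation), including mcrA (0.97, SE 0.38) and tfaP (1.03, SE 0.41). The e14 call was lost under 13 of 19 alternatives: the median was 0.37 without WT replicate 1, 0.70 without WT replicate 2, 0.19 without G181D replicate 1, and 0.52 without either R258C replicate, with the replicate number as block, with only the groups compared or with array weights. It was 0.20, 0.30 and 0.24 with normexp, median scaling and quantile normalization, 0.47 with the stricter filter and 0.45 with the gene column of the files. Without WT replicate 2 and G181D replicate 2 together the e14 median was 0.87 and passed.

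Among single genes higher in G181D, none passed. The largest statistics belonged to ilvM, a subunit of acetolactate synthase (2.07, SE 0.43, adjusted p 0.445), ybbC (1.84, SE 0.41), ybfB (1.64, SE 0.39), yfcC (1.52, SE 0.40) and ytfI (1.76, SE 0.47). nusG, a transcription elongation factor, had a change of 0.44 (SE 0.66). tnaA, for tryptophanase, had a change of -2.15 (SE 1.29), with a level of 3.24 in G181D replicate 1 and between 6.56 and 7.85 on the other 5 arrays.

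The comparison of R258C with WT asked the same of the R258C change. Flagellar and chemotaxis genes were again lower, by a median of -2.12, with 28 of 29 below 0 (camera adjusted p 3.6e-19, and adjusted p = 0.706 with an estimated correlation). In 27 of the 29 both R258C arrays lay below both WT arrays, and fliJ and fliO had changes of -1.69 (SE 0.36) and -1.71 (SE 0.37). The median was -1.47 without the library labelled WT replicate 2. RpoS-dependent stress genes were lower by a median of -1.15, 13 of 15 below 0 (adjusted p 1.1e-04, and adjusted p = 0.706 with an estimated correlation), including osmC (-1.73, SE 0.42), aidB (-1.30, SE 0.48) and gadE (-2.28, SE 0.92). The RpoS median was -0.51 without WT replicate 1, where it did not pass, and -0.58 without R258C replicate 2.

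Iron uptake genes were higher in R258C by a median of 1.04, all 14 above 0 (adjusted p 5.3e-05, and adjusted p = 0.719 with an estimated correlation), including the ferrichrome transport genes fhuB (1.43, SE 0.73) and fhuD (1.33, SE 0.70) and the enterobactin genes entF (0.93, SE 0.50) and entA (0.69, SE 0.40). The iron median was 1.58 without WT replicate 1 or without R258C replicate 1, 0.57 without WT replicate 2 (with or without G181D replicate 2), 0.56 without R258C replicate 2 and 0.58 with normexp. Ribosomal protein genes were higher by a median of 0.92, all 13 above 0 (adjusted p 0.00783, and adjusted p = 0.933 with an estimated correlation), such as rplA (1.07, SE 1.02) and rplL (1.00, SE 0.83). Elongation and termination factor genes were higher by a median of 0.68, 8 of 9 above 0 (adjusted p 0.0311, and adjusted p = 0.706 with an estimated correlation), including suhB (2.69, SE 1.20), nusB (1.29, SE 0.69) and rpoB (1.06, SE 0.92). The ribosomal median was 1.12 without WT replicate 1, 0.71 without WT replicate 2 and 0.35 without R258C replicate 2, where it did not pass, and 1.41 without R258C replicate 1. The elongation factor median was 0.98 without WT replicate 1 and 0.35 without R258C replicate 2, where it did not pass, and 0.50 with the gene column of the files, where it did not pass either.

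Rac prophage genes were higher in R258C by a median of 2.11, all 11 above 0 (adjusted p 5.3e-05, and adjusted p = 0.706 with an estimated correlation). The Rac median was 0.06 without the library labelled WT replicate 2, with or without G181D replicate 2, and did not pass. It was 4.19 without WT replicate 1 and 0.35 with normexp. Because 19.5% of probes in the Rac stretch were well above background in the library labelled WT replicate 2, the 2.11 and 4.19 are not exact changes. Fimbriae and curli genes were higher by a median of 0.40, 13 of 18 above 0 (adjusted p 0.00725, and adjusted p = 0.706 with an estimated correlation), including fimA (1.96, SE 0.86) and fimH (1.40, SE 0.55). The fimbriae median was 0.49 without WT replicate 2, where it did not pass, 0.73 without WT replicate 1, 0.64 without R258C replicate 2, 0.07 with normexp, 0.73 with the stricter filter and 1.72 with the gene column of the files.

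No single gene passed in R258C with limma (smallest adjusted p 0.771). At an unadjusted p under 0.05 there were 85 genes, 12 higher and 73 lower. The count was 32 without WT replicate 1, 23 higher and 9 lower, and 22 of these genes lie in the stretches without signal in the library labelled WT replicate 2. The largest statistics among lower genes belonged to ygiM (-2.07, SE 0.43), yahO (-2.44, SE 0.51), fliJ, fliO and yfeK (-2.62, SE 0.60). Among higher genes they belonged to ilvM (1.35, SE 0.43), ykgG (1.18, SE 0.39), ykgF (1.22, SE 0.44), endA, a nuclease gene (1.57, SE 0.53), and rzpD (2.40, SE 0.89). Of the tested genes, 46.9% had both R258C arrays on 1 side of both WT arrays, and 24.9% had both G181D arrays so. Chance gives 33.3% only where all arrays vary alike and independently. Replicate differences had an SD of 1.55 in WT, 1.42 in G181D and 0.52 in R258C, and correlated at 0.52 between WT and G181D. Neither share can therefore be read against 33.3%.

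**Figure D4:**
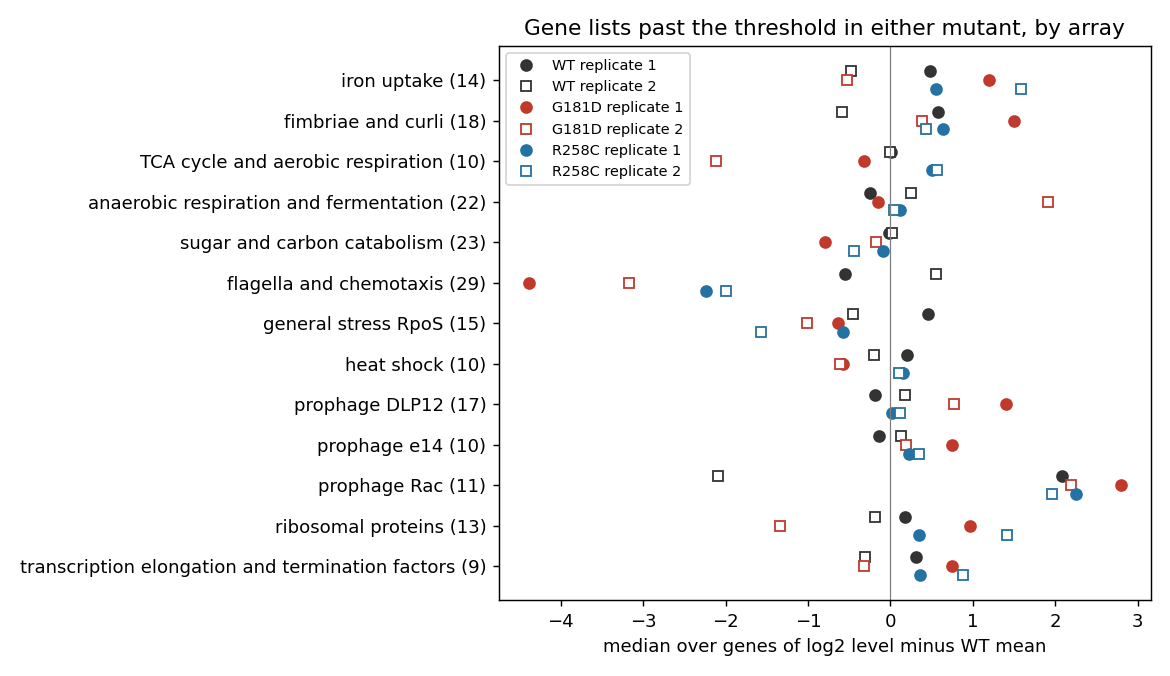
Median over the genes of a list of the log2 level minus the WT mean, by array, for the lists past the camera threshold in either mutant (number of genes in brackets; filled circles replicate 1, open squares replicate 2). For flagella and chemotaxis the G181D arrays lie at -4.39 and -3.18 and the R258C arrays at -2.24 and -1.99. For Rac the WT arrays lie at 2.09 and -2.09.

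The direct comparison of R258C with G181D asked whether the 2 forms differ. Flagellar genes were higher in R258C than in G181D by a median of 1.80, 24 of 29 above 0 (camera adjusted p 8.8e-16, and adjusted p = 0.567 with an estimated correlation), and 11 passed when adjusted over the list alone. The largest statistics were those of fliJ (2.56, SE 0.36), fliP (2.43, SE 0.37), fliQ (2.24, SE 0.36), fliI (2.12, SE 0.35) and fliO (2.21, SE 0.37), each with an adjusted p of 0.536. The flagellar median was 0.87 without G181D replicate 1 and 1.18 with normexp. Heat shock genes were higher by a median of 0.96, 8 of 10 above 0 (adjusted p 1.3e-04, and adjusted p = 0.471 with an estimated correlation), including groL (1.77) and htpG (1.64), and 1 gene passed over the list alone. The heat shock median was 0.59 with the gene column of the files. TCA cycle genes were higher by a median of 1.74, all 10 above 0 (adjusted p 3.5e-08, and adjusted p = 0.567 with an estimated correlation), including sucD (2.28). The TCA median was 0.82 without G181D replicate 2, with or without WT replicate 2, and 2.66 without G181D replicate 1.

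Prophage DLP12 genes were lower in R258C than in G181D by a median of -0.81, 14 of 17 below 0 (adjusted p 4.9e-05, and adjusted p = 0.567 with an estimated correlation), including appY (-2.76), ybcM (-1.50) and tfaX (-1.36). Without G181D replicate 1 the DLP12 median was -0.62 and did not pass. The other calls of this comparison rested on single arrays. Anaerobic genes had a median of -1.58, all 22 below 0 (adjusted p 1.6e-04, and adjusted p = 0.729 with an estimated correlation), which was -0.13 without G181D replicate 2 (with or without WT replicate 2) and did not pass, and -2.60 without G181D replicate 1. Ribosomal protein genes had a median of 0.93, all 13 above 0 (adjusted p 0.00396, and adjusted p = 0.797 with an estimated correlation), which turned to -0.22 without G181D replicate 2 (with or without WT replicate 2), was 0.42 without R258C replicate 2 and 0.70 with quantile normalization, none of which passed, and was 1.90 without G181D replicate 1. Iron uptake genes had a median of 0.73, 13 of 14 above 0 (adjusted p 0.00808, and adjusted p = 0.804 with an estimated correlation), which turned to -0.20 without G181D replicate 2 (with or without WT replicate 2), and was 0.21 without R258C replicate 2, 0.19 with normexp and 0.24 with the gene column of the files, none of which passed. It was 1.70 without G181D replicate 1 and 1.24 without R258C replicate 1. No single gene passed with limma (82 at an unadjusted p under 0.05, smallest adjusted p 0.536). The count was 8 without G181D replicate 1, all lower, and 39 without WT replicate 2 and G181D replicate 2 together, 23 higher and 16 lower. ybbC (-1.67) and yoaC (-1.25) had the other large negative statistics.

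Other lists that passed in neither mutant had median changes in G181D and R258C as follows. They were 0.74 and 0.34 for prophage Qin, 0.08 and -0.03 for the P4-like prophages, and 0.12 and -0.20 for CPS-53, CPZ-55 and KpLE2. In Qin, flxA, a gene with a flagellar promoter, stood at 7.70 in the library labelled WT replicate 2 and between 0.23 and 2.59 on the other arrays. Leader-attenuated operons had -0.11 and -0.03, SOS genes 0.05 and 0.06, with umuC, for an error-prone polymerase, 2.15-fold and 1.19-fold higher, and envelope stress genes 0.18 and -0.46. Nucleotide synthesis genes had 0.15 and 0.60, and arginine and methionine synthesis genes 0.15 and 0.13, with metF at 1.45 and 0.67 (SE 0.47). The mean had the other sign than the median for the P4-like prophages, the leader-attenuated operons and nucleotide synthesis in G181D, and for Qin and the anaerobic genes in R258C. The marker list had 2 measured plus-strand members, with mean changes of 0.02 and 0.03. The nusA operon and the surface polysaccharide operons had none; their 7 and 36 minus-strand members had opposite-strand medians of 1.31 and 0.05 in G181D and 0.84 and 0.11 in R258C. Without the library labelled WT replicate 2 the medians of these 2 lists were 0.69 and 0.32 in G181D and 0.44 and 0.35 in R258C, and without WT replicate 1 those of the polysaccharide operons were -0.28 and -0.12.

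Both responses were compared across the 1927 genes. Pearson's r was 0.594 and Spearman's correlation 0.42, across genes, which are not independent replicates. Because both responses share the WT arrays, simulated unchanged mutants also gave a mean r of 0.501 (0.376 to 0.600 over 100 draws) and a mean Spearman correlation of 0.451. The covariance was 0.553, above all 100 draws (mean 0.391, 0.247 to 0.504), while r lay inside its range and the difference between the WT arrays alone would give a covariance of 0.598. A relation beyond the shared WT arrays was thus neither shown nor excluded. Pearson's r was 0.132 without G181D replicate 1. At an unadjusted p under 0.05, 32 genes were lower in both mutants (2.12 if independent) and 2 were higher in both (0.268), counts that share the WT arrays too.

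Signal along the gene and on the opposite strand was compared because NusA acts in elongation and termination. With limma, no gene of 1607 passed for the difference between its last and first part in G181D (63 at an unadjusted p under 0.05) or in R258C (44). Of 1998 minus-strand genes, none passed for opposite-strand signal in G181D (142 at an unadjusted p under 0.05, 131 of them higher) or in R258C (85). Over all 1998 genes the median change was 0.24 in G181D and 0.05 in R258C. Their median level was -2.90 in WT replicate 1 and -2.52 in G181D replicate 1. The tilt to higher genes in G181D, here and without WT replicate 2 and G181D replicate 2, was not separated from this general shift. The shift depends on the scaling: with median scaling the infB change in G181D was 0.90. infB and rimP, next to nusA, had opposite-strand changes of 1.12 (SE 0.39) and 1.31 (SE 0.50) in G181D, and nusA itself of 2.55 (SE 1.80), none of which passed. Without the library labelled WT replicate 2 the changes of infB and rimP were 0.71 and 0.69, and that of nusA turned to -0.39. The nusA change in G181D was 5.49 without WT replicate 1 and 1.67 without G181D replicate 2. In R258C infB, rimP and nusA had changes of 0.84, 1.39 and 3.11, and of 0.43, 0.77 and 0.17 without the library labelled WT replicate 2. Without WT replicate 1, 2 genes passed in each mutant for the difference along the gene, 1 higher and 1 lower. For opposite-strand signal 26 then passed in G181D (14 higher, 11 in the stretches) and 22 in R258C (10 higher, 7 in the stretches). Without G181D replicate 1, 2 passed in G181D for opposite-strand signal, both higher. Without WT replicate 2 and G181D replicate 2 together, the counts were 121 in G181D (34 higher) and 62 in R258C (27 higher) along the gene, and 64 in G181D on the opposite strand (60 higher), in a fit with 1 residual degree of freedom.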

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

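The plan named no test of the lists between the mutants. The tests of explanations in this part were chosen after the results they examine had been seen, as was the rule used to find stretches without signal.

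A test of the difference between the mutants picked out 7 lists, as medians of R258C minus G181D: flagella and chemotaxis 1.80, TCA cycle 1.74, heat shock 0.96, ribosomal proteins 0.93, iron uptake 0.73, prophage DLP12 -0.81 and anaerobic respiration -1.58. Each passed camera at the preset correlation and none with an estimated correlation. Probes that touch no annotated gene were used in no gene comparison and were well above background in 71.6% or more of cases on each array, against 0.333% to 0.917% of negative controls.

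The first pattern is the lower flagellar signal in both mutants. Leaving out the arrays labelled WT replicate 2 and G181D replicate 2 gave a median change of -3.91 in G181D. Leaving out each alone moved it in opposite directions, to -3.46 without WT replicate 2 and to -4.39 without G181D replicate 2. The fall in G181D thus stayed without these arrays, which argues against them as its main source, though WT replicate 2 added to it. In R258C the median was -1.47 without both and -2.12 with all arrays, so part of the fall there also came with WT replicate 2. The largest move of the list's median, 24.4%, came from normexp background correction in G181D (-3.92 to -2.96). It lies between the bounds of 20% and 50% set for the test, so a partial contribution of background correction stays open. With median scaling and quantile normalization the medians were -4.14 and -4.07 in G181D, and -2.23 and -2.08 in R258C, against -2.12 in the main fit. The fall thus stayed under both of these scalings. Median scaling moves every gene alike, and took the median of all tested genes in G181D only from 0.01 to -0.21. It could therefore not have removed a fall of this size, and scaling as a source stays undecided. The list passed under all 3 alternatives in both mutants. Slide and scan cannot be told apart from the groups, since 0 slides held more than 1 group and 0 groups spanned more than 1 slide. An effect of the NusA forms on flagellar transcription may be present, as may a difference between cultures that arose in strain construction, and neither was tested.

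The second pattern is the library labelled WT replicate 2, which lacks the high nusA signal and lacks signal in 2 stretches of 18.4 and 48.4 kb. Outside them its signal was also low in the bins at 1397000 to 1399000 (-5.99 to -5.45), which the rule of at least 3 genes did not take up. That library also has opposite-strand signal over the 22 minus-strand flagellar genes (median -0.19, against -3.93 to -3.50 on the other arrays). Outside the stretches its share of probes above background was only 0.668 points below the mean of the other 5 arrays. That share tests brightness weakly: this array had the lowest 75th percentile (290), yet all arrays lay between 94.7% and 97.6%. Within this array the share was 95.3% outside the stretches and 19.6% inside, against 93.5% or more inside on the others. This argues against weak hybridisation of the whole array as the source of the stretches, although they were chosen for low signal. Whether the library was exchanged with another array of the series stays open. The stretches would move with the sample, so their number on the other 5 arrays, 0, cannot decide it. By the labels every group carried a NusA plasmid. An exchange would therefore change the group of this library, but would not by itself account for its missing nusA signal. DNA segments absent from that culture and genes that were silent in it both stay open: 94.4% of the 54 genes without signal on that array alone lay in the 2 stretches, but the stretches were built from those genes. A culture of another origin, without the plasmid, also stays open, and no biological explanation was tested.

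The third pattern is that, over lists, opposite-strand signal of minus-strand genes followed the sense signal of plus-strand genes of the same list. Over 21 lists and both mutants (42 pairs, which share the WT arrays) Pearson's r of the median changes was 0.842 and Spearman's correlation 0.662 (permutation p = 1e-04, two-sided over lists, the smallest that 10000 permutations can give), and without the flagellar and Rac lists they were 0.595 and 0.543. Without the library labelled WT replicate 2, r was 0.460 over all lists and 0.635 over the lists other than the flagellar one. The flagellar list then did not follow: its opposite-strand change was 0.45 in G181D and 0.21 in R258C, where its sense change was -3.46 and -1.47. Label made from the sense RNA of the same gene therefore stays open, as does antisense transcription that changes with the sense transcript, which was not tested.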

How the results depend on the processing

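The gene column of the files, array weights and the omission of WT replicate 2 with G181D replicate 2 were added after the data had been seen. The flagellar list kept its direction and passed under all 19 alternatives of the values, the samples or the fit in all 3 comparisons, as did DLP12 in G181D, iron uptake in R258C, and heat shock and the TCA cycle in R258C against G181D. Genes passing in G181D were 0 with normexp, no filter, the median over probes, the replicate number as block, only the groups compared, the trended robust prior, the gene column and array weights, where the cause was not tested. Genes passing were 44 in G181D and 39 between the mutants without WT replicate 2 and G181D replicate 2, a fit with fewer samples. There the lists between the mutants were 11, genes changed along their length 121 and 62, and opposite-strand genes in G181D 64. With an estimated correlation and by fry's test for a shared direction, 0 lists passed in each comparison (smallest adjusted p 0.583, 0.706 and 0.471, and 0.224, 0.399 and 0.170). Fry's test without regard to direction passed 2 lists in G181D and 0 in each other comparison. Leaving out each array gave 0 to 47 genes in G181D, 0 to 32 in R258C, 0 to 8 between them, 6 to 12, 4 to 8 and 7 to 10 lists, 0 to 2 genes along the gene in each mutant, 0 to 26 and 0 to 22 opposite-strand genes, and a correlation of 0.132 to 0.848. In a group left with 1 array, that array is assumed to vary like the other groups. Direction reversed without G181D replicate 2 for ribosomal proteins in G181D (0.97) and between the mutants (-0.22), anaerobic genes in G181D (-0.15), and iron uptake (-0.20) and, by camera's direction, anaerobic genes (-0.13) between the mutants. Without WT replicate 2 as well, ribosomal proteins had 0.93 in G181D and -0.22 between the mutants, where iron uptake had -0.20 and anaerobic genes -0.13. The anaerobic median in G181D for that fit is given in the Results. Leaving out G181D replicate 1 gave the other end of these ranges, in the order first named: -1.34, 1.90, 1.92, 1.70 and -2.60. The cause was not tested. Values that did not pass changed sign in 213 of 5959 gene and 79 of 797 list comparisons. The replicate number is also the position on the slide; the replicate differences correlated at 0.52 between WT and G181D, -0.03 between WT and R258C and -0.30 between G181D and R258C, and the block fit had a smallest adjusted p of 0.0820 in G181D, so an effect of position stays open. The slide as a random block was not run, since each slide held 1 group. Signal over background did not limit most genes: 91.0% or more of spots were well above it.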

Other observations

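The test of signal past gene ends was planned before its result was seen, and the other values in this part were looked up after the data had been seen.

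G181D replicate 2 differed from its partner in genes of respiration without oxygen. The median change against the WT mean of the anaerobic list was 1.92 on that array and -0.15 on G181D replicate 1, and that of the TCA cycle list was -2.12 and -0.32. Its level of dmsA was 4.37, against -1.41 on G181D replicate 1. G181D replicate 1 had tnaA at 3.24 and tnaB, a tryptophan transporter gene, at -0.38, against 7.23 and 3.61 on G181D replicate 2. flu, for the surface adhesin antigen 43, stood at 2.74 and -1.94 in WT, -2.82 and -2.92 in G181D, and 1.85 and 0.01 in R258C. Ribosomal protein genes differed between replicates in the mutants, with medians against the WT mean of 0.97 and -1.34 in G181D, and 0.35 and 1.41 in R258C.

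Less termination at gene ends in the mutants would raise the signal between a plus-strand gene and a following minus-strand gene relative to the gene. Over 79 such gaps, the median of gap minus gene was -0.97 and -1.57 in WT, -0.94 and -1.36 in G181D, and -0.87 and -1.03 in R258C. The median change was 0.196 in G181D and 0.379 in R258C, which lies between the bounds set for the lower value, and no gap passed with limma (5 and 2 at an unadjusted p under 0.05). G181D replicate 2 and R258C replicate 2 lay below WT replicate 1. The test is open: the value neither shows more signal past gene ends nor excludes it, and the library labelled WT replicate 2 had the lowest median.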
